A study of Mus musculus with 10 samples.

How the data were processed

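Messenger RNA was measured in the hypothalamus of male C57BL/6J mice, an inbred laboratory strain, with the Clariom S Mouse array, a 1-colour oligonucleotide array on which a probe set stands for a transcript. The labels give 5 samples at an age of 24 weeks (Young 1 to Young 5) and 5 at 138 weeks (Old 1 to Old 5). Biotin-labelled cDNA was made from 100 ng of total RNA per sample, per the labels' protocols. A code in each sample's description begins with 8 for the Young and 120 for the Old samples; its meaning is not given in the sources used here, and samples were grouped by title and age. The labels do not say that each sample was a separate animal, so p-values measure the spread between these samples, which may in part be technical. No batch or array date was used here.

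The deposited values are 1 number per probe set and array. They were read as log2 signal, from their range of 5.00 to 12.97 and the near-identical quartiles of the 10 arrays; the deposited file does not name the base, so each fold rests on that reading. As deposited, the log2 values were already reduced to 1 number per probe set and array; the background correction, normalization and summarisation by which the authors made them are not given in the sources used here. Array medians lay between 6.778 and 6.783. Over the genes tested, the mean of the Old array medians was 0.0014 log2 above that of the Young array medians. No background or detection call was used, so nothing is said here about which probe sets lay above background, and the number of arrays limits the precision.

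The deposited table holds 22206 probe sets. For 21741 of them (97.9%) the population SD over the 10 arrays was 1e-05 log2, within a tolerance of 1%; these are called collapsed below. A further 342 (1.54%) had an SD of at least 0.01 log2 and are called varying, and 123 lay between. A collapsed probe set has a level, but its deposited values cannot show the size of a difference between ages, and a test that finds none there says nothing about the transcript. How far the differences of varying probe sets were also shrunk is unknown, so their folds describe the deposited values.

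Probe sets were named through the platform's annotation, which pairs 19572 with 1 gene symbol, 0 with several and leaves 2634 unnamed here. All 19572 gene identifiers matched the RefSeq table of assembly GRCm38.p6, and 0 symbols changed; no coordinates were used, because no source used here names the build of the array. Where a gene had several probe sets, the one with the highest mean over the 10 arrays was kept, which left 19505 genes. Of these, 19118 were collapsed, 276 varying and 111 between.

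Old was compared with Young for all 19505 genes with limma (version 3.58.1, in R 4.3.3) using lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This fit was fixed before the data were examined, as were the gene lists, the rule for named genes and most alternatives. Because the collapsed genes set the spread to which limma moves each gene (a prior SD of 7.0e-06 log2 with 1.04 prior degrees of freedom), a second fit on the 276 varying genes alone was added after seeing the data, and its adjusted p is named as such wherever it is given. Differences are Old minus Young in log2 units, with limma's standard error (SE). A gene "rose" or "fell" where the adjusted p of the fit named was under 0.05. For single varying genes a 2-sided exact permutation test over the 252 ways of labelling the 10 arrays was also run; its smallest possible p with 5 against 5 is 0.00794.

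Gene lists for cell types, hypothalamic peptides, immune, synaptic and metabolic groups were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 41 lists with at least 5 measured genes. Camera was also run with an estimated correlation and on the varying genes alone (16 lists with at least 3 varying members), and fry was run beside it. Of the 903 listed genes, 804 were measured and 96 varied. Named genes are the 10 largest rises and falls among genes past the threshold whose groups did not overlap (10 and 6 genes). To these were added up to 4 members of each list past the threshold by smallest p, up to 2 members past the threshold of any other list, and 16 genes fixed whatever their result. Of those 16, Agrp and Kiss1 were not analysed here. Genes named outside this rule were chosen after their values were seen, and the text says so.

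The procedure was tested on simulated data. With ordinary noise, 100 of 19505 genes changed by 0.3 log2 and 100 by 0.6 log2, it recovered 95% of the smaller and 100% of the larger changes, with 10 false calls. With values collapsed like the deposited ones and 50 of the 276 varying genes changed by each size, the fit to all genes recovered 54% and 80%, with 2 false calls. The fit to the varying genes alone recovered 82% and 96%, with 3 false calls.

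Alternatives covered quantile normalization, median centring, leaving out the dimmest 33.3% or 50% of genes, a trended robust prior, array weights, an unmoderated test per gene, all probe sets, the mean of a gene's probe sets, stricter thresholds, the replicate number as a block and each array left out in turn. Added after seeing the data were an SD of at least 0.05 log2, Young 3 and Young 5 left out together, and the level of Slc6a3 as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.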

Results

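The hypothalamus of mice aged 24 weeks and 138 weeks was compared to ask which transcripts change with age. Each group held 5 arrays. No 2 arrays were identical, and over the 276 varying genes the mean correlation of an array with the others of its group ran from 0.953 (Young 5) to 0.992 (Old 4). The first 3 principal components of the varying genes held 45.0%, 25.9% and 11.7% of their variance. In the deposited values 97.9% of probe sets had collapsed to 1 common, very small spread, so the comparison below is in effect one of 276 genes.

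**Figure D1:**
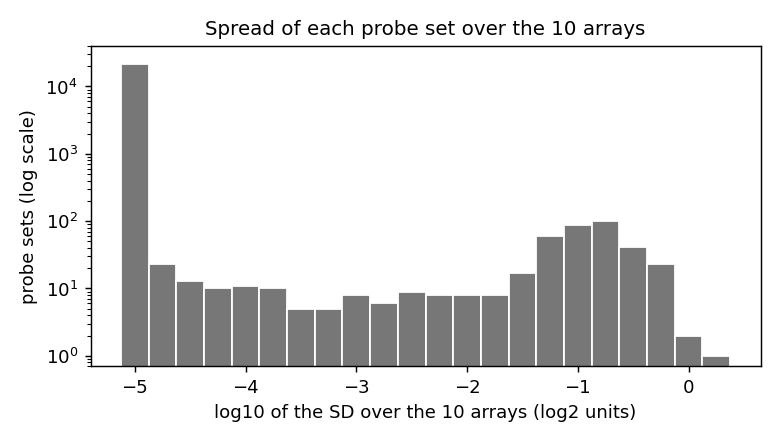
Number of probe sets (log axis) by the log10 of their population SD over the 10 arrays, in log2 units. The tall bar near -5 holds nearly all of the 21741 collapsed probe sets, and the 342 varying probe sets lie at -2 and above.

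Among genes past the threshold over all genes, the 10 largest rises in the Old hypothalamus were those of C4b, Ifit3, Ifit3b, Ctss, Lyz2, Serpina3n, C4a, Mpeg1, B2m and Pcdhb14. The largest was that of C4b, a complement component made by glia, from 7.69 ± 0.086 to 8.82 ± 0.15 log2 (SD, n = 5), a difference of 1.13 (SE 0.072) or 2.19-fold. Ifit3 and Ifit3b, antiviral effectors induced by interferon, rose by 1.12 (SE 0.10) and 1.04 (SE 0.059), or 2.18-fold and 2.06-fold. Ctss, the microglial protease cathepsin S, rose 1.88-fold, Lyz2, a lysozyme of myeloid cells, 1.80-fold, and Serpina3n, a protease inhibitor of reactive astrocytes, 1.75-fold. C4a rose 1.72-fold, the macrophage pore protein gene Mpeg1 1.63-fold, B2m, the invariant chain of MHC class I, 1.58-fold, and Pcdhb14, a beta protocadherin, 1.51-fold. In each of these 10 genes all 5 Old values lay above all 5 Young values, and adjusted p ran from 0.000172 (Ctss, Ifit3b and Pcdhb14) to 0.0132 (Lyz2). The call of Lyz2 was lost when Young 1, Young 2, Young 4 or Old 4 was left out, with adjusted p from 0.0521 to 0.0613, and that of Serpina3n without Young 3 and Young 5 together (0.0747). In these fits the difference of Lyz2 was 0.81 to 0.82 (0.84 with all arrays) and that of Serpina3n 0.83 (0.81 with all arrays).

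Fewer transcripts were lower in the Old hypothalamus, and the falls were smaller. Kcnj10, the inwardly rectifying potassium channel Kir4.1 of astrocytes and oligodendrocytes, fell from 9.90 ± 0.027 to 9.42 ± 0.13 log2 (SD, n = 5), a difference of -0.48 (SE 0.056, adjusted p = 0.0104; 0.168 without Young 3 and Young 5). The astrocyte gene Ntsr2, which encodes a neurotensin receptor, differed by -0.30 (SE 0.027, adjusted p = 0.00241), and Ccnd2, which encodes cyclin D2, by -0.27 (SE 0.028, adjusted p = 0.00395). The rule also named Slc7a10, Ywhah and Tas2r104 as lower, but their differences were under 0.001 log2. Tas2r104 was collapsed, and Slc7a10 and Ywhah lay between collapsed and varying.

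**Figure D2:**
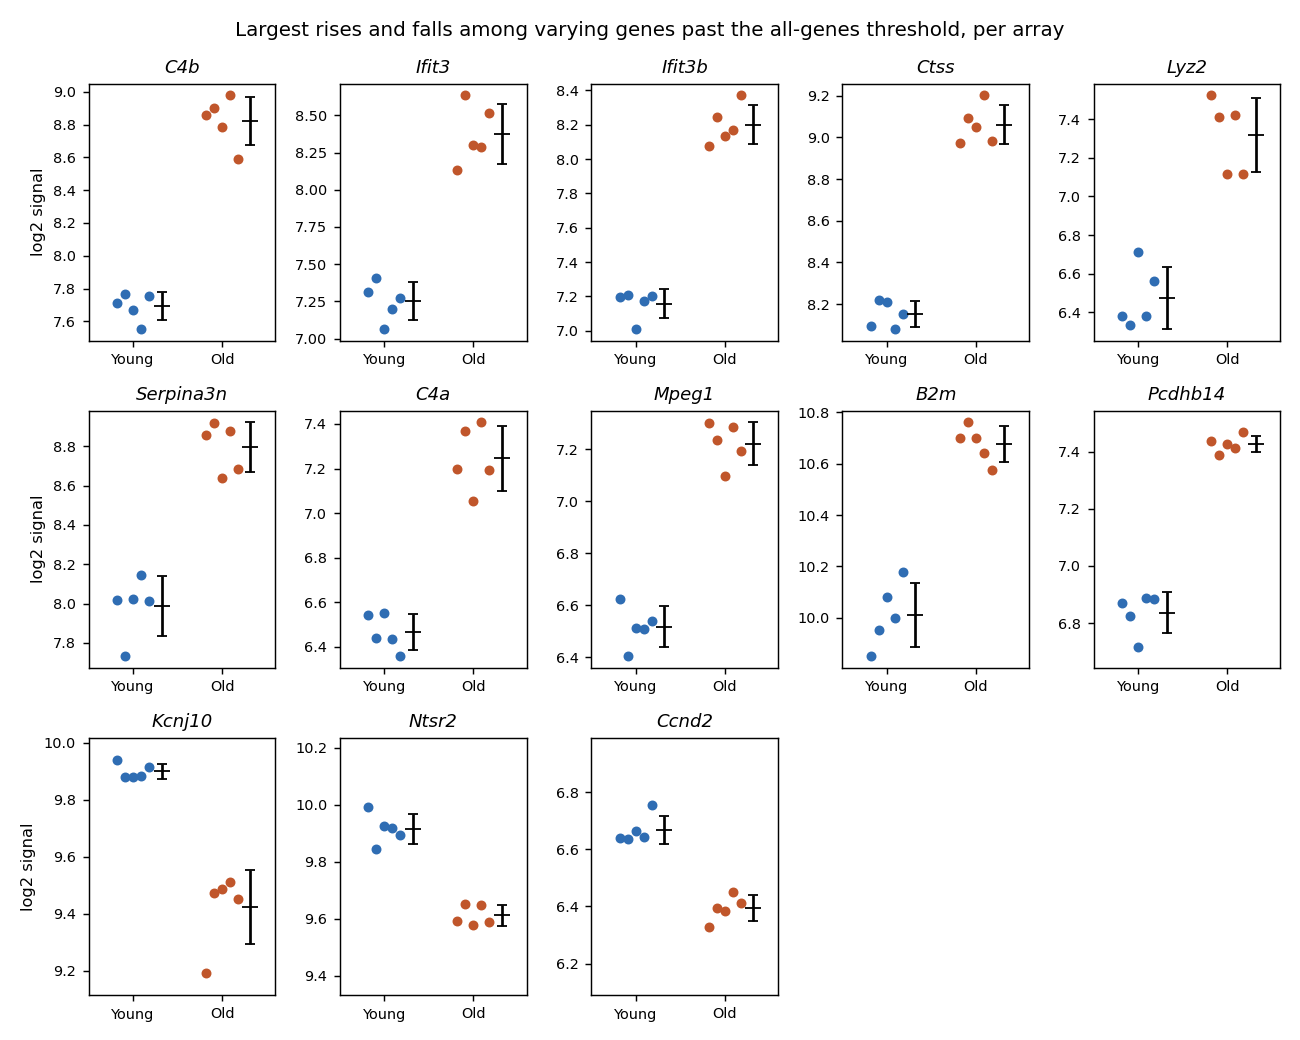
Log2 signal of each array (points) for the varying genes with the largest rises and falls among those past the threshold over all genes, with the group mean and SD (bars, n = 5) beside the points. Young and Old values do not overlap in any panel; C4b shows the largest difference, 1.13 log2.

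Over all 19505 genes, 37 rose and 6 fell, and 1331 had an unadjusted p under 0.05. Of these 43 genes, 34 were varying (31 rose and 3 fell). The other 9 were C1qc, Trem2, Dock2, Xaf1, Pcdhb5 and Aspdh, which rose, and Slc7a10, Ywhah and Tas2r104, which fell; their largest difference was 0.012 log2, and their names were listed after their values were seen. In the fit to the 276 varying genes alone, chosen after seeing the data, 68 genes rose and 31 fell, among them all 34 varying genes above. The groups did not overlap in 57 varying genes that were higher and 20 that were lower in Old (27.9% of varying genes), where chance gives 0.794%; among collapsed genes the share was 0.858%. Quantile normalization, which raised the median SD of collapsed genes from 1e-05 to 0.00074 log2, gave 154 genes higher and 6464 lower. Rises were then 2.33% of calls against 86.0% in the deposited values, but 6472 of these calls were collapsed genes moved by the normalization. In the varying genes alone it gave 66 higher and 36 lower, against 68 and 31, so the balance there changed little.

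The beta protocadherins, a cluster of neuronal cell-adhesion genes, ranked higher in Old (camera adjusted p = 2.43e-12, and 0.0015 with an estimated correlation). That correlation was -0.037, under the preset 0.01, so the larger adjusted p does not come from correlation between members. It was under 0 in each of the 5 lists past the threshold over all genes. Adjusted over the list alone, 9 members rose. Of 20 measured members 8 rose, 0 fell and 12 did not pass. Those that rose were 7 of the 8 varying members and Pcdhb5, which did not vary and differed by 6.7e-05 log2. The other varying member, Pcdhb20, was higher by 0.23 (adjusted p = 0.0611), and the values of the 12 members that did not vary cannot show the size of a change. Pcdhb14 rose by 0.59 (SE 0.032), Pcdhb8 by 0.48 (SE 0.044), Pcdhb2 by 0.27 (SE 0.026) and Pcdhb4 by 0.26 (SE 0.022). These genes are similar in sequence, so a probe set may also take signal from a neighbouring family member, and the same holds for the pairs C4a and C4b, and Ifit3 and Ifit3b.

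The reactive astrocyte list ranked higher in Old (camera adjusted p = 0.000702; adjusted p = 0.039 with an estimated correlation). Of its 21 measured members 4 rose and 0 fell, with 5 adjusted over the list alone: C4b, Serpina3n, H2-D1, a classical MHC class I gene, by 0.46 (SE 0.032), and Gfap, the astrocyte intermediate filament, by 0.44 (SE 0.065, 1.36-fold, adjusted p = 0.0396). The call of Gfap was lost when any single array other than Young 5 or Old 5 was left out, with adjusted p from 0.094 to 0.142 and a difference of 0.41 to 0.45. In the varying genes alone its adjusted p was 0.00061. Of the general astrocyte list only Ntsr2 passed among 13 measured genes. That list did not pass with camera (adjusted p = 0.197), but with fry it passed, lower in Old (adjusted p = 0.0102). Its 4 varying members were split, 2 higher and 2 lower in Old. In the varying genes alone it did not pass with camera (adjusted p = 0.241), so a general fall of astrocyte genes is not shown.

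The complement list ranked higher in Old (camera adjusted p = 0.011; adjusted p = 0.0881 with an estimated correlation). Of 20 measured members 2 rose, C4b and C1qc, with 4 adjusted over the list alone; C1qc, a chain of the initiating C1q complex, differed by only 0.0059 log2 and was not a varying gene. The other C1q chains were higher by 0.34 (C1qa, SE 0.056) and 0.29 (C1qb, SE 0.048); each had an adjusted p of 0.0719 over all genes and of 0.00146 and 0.00148 in the varying genes alone. Without Old 3 the list had an adjusted p of 0.0515, and without Young 3 and Young 5 it had 0.0513.

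The list of disease-associated microglia, genes that microglia raise near damage, ranked higher in Old (camera adjusted p = 0.0204; adjusted p = 0.102 with an estimated correlation). Of 19 measured members 2 rose, Lyz2 by 0.84 (SE 0.10) and Trem2, a lipid-sensing receptor, by 0.0017 log2 without varying; 5 passed when adjusted over the list alone. The iron-storage gene Fth1 was higher by 0.11 (SE 0.021, adjusted p = 0.114), a difference that quantile normalization removed, and the lipid carrier Apoe by 0.092 (SE 0.021, adjusted p = 0.242). In the varying genes alone their adjusted p was 0.00828 and 0.0245, and 3 of the list's 4 varying members rose. The list's call was lost without Young 1 (adjusted p = 0.0655), Young 3 (0.158) or Old 3 (0.0515), without Young 3 and Young 5 together (0.0692), with quantile normalization (0.0859) and in the varying genes alone (0.0736). Of 14 measured genes of homeostatic microglia 0 varied, so these values cannot show whether they changed.

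The MHC class I list ranked higher in Old (camera adjusted p = 0.0379; adjusted p = 0.138 with an estimated correlation). Of 14 measured members 3 rose, also 3 adjusted over the list alone: B2m by 0.66 (SE 0.06), H2-D1 by 0.46 and H2-K1 by 0.056 (SE 0.0058, adjusted p = 0.00395; 0.0547 without Young 3 and Young 5). H2-T23, a non-classical member, was collapsed at 7.17 log2. The call was lost when Young 2, Young 3, Young 5, Old 1, Old 2 or Old 3 was left out, with adjusted p from 0.0533 to 0.146, without Young 3 and Young 5 together (0.167), and with quantile normalization (0.356) or the dimmest 33.3% of genes left out (0.0669). In the varying genes alone 5 lists passed: beta protocadherins, reactive astrocytes, complement, MHC class I and interferon-stimulated genes, and 1 of them, the beta protocadherins, with an estimated correlation (adjusted p = 0.0152).

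Interferon-stimulated genes did not pass over all genes with camera (adjusted p = 0.415), where their mean statistic was above 0 and their median below. With fry the list passed, higher in Old (adjusted p = 0.00648). Of 29 measured members 3 rose (Ifit3, Ifit3b and Xaf1), with 6 adjusted over the list alone. All 5 varying members rose in the varying genes alone, where the list had an adjusted p of 0.00192, and 0.219 with an estimated correlation; they include Oasl2, by 0.42 (SE 0.071), and Ifitm3, by 0.30 (SE 0.064). Ctss was the member that rose of the 8 measured MHC class II genes (camera adjusted p = 0.201) and of the 29 measured lysosomal genes (camera adjusted p = 0.419). With fry the MHC class II list passed, higher in Old (adjusted p = 0.0184), and the lysosomal list did not (0.0674). Ctss was the only varying member of the MHC class II list. Its other 7 measured members did not pass among genes that did not vary (camera adjusted p = 0.953), so the fry result does not show a rise beyond Ctss. Of 55 measured cytosolic ribosomal protein genes, Rpl4 rose by 0.13 (SE 0.016) and Rps7 by 0.065 (SE 0.0098); the list did not pass (adjusted p = 0.415). The call of Rps7 was lost when any single array other than Old 2 was left out (adjusted p from 0.0852 to 0.149), and that of Rpl4 without Young 1 (0.0549) or Young 3 (0.0587). The differences in these fits were 0.059 to 0.068 for Rps7 and 0.12 to 0.13 for Rpl4. Without Young 3 and Young 5 together, Rpl4 had an adjusted p of 0.168 and Rps7 of 0.355.

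**Figure D3:**
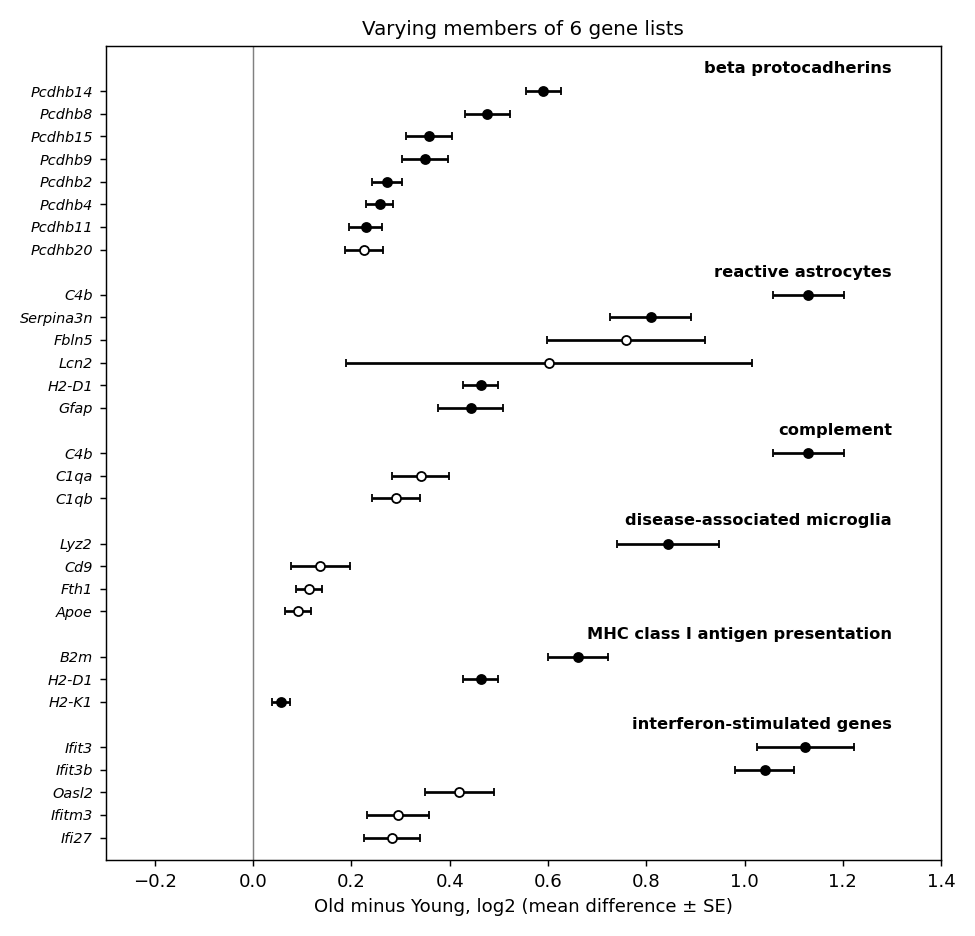
Old minus Young difference in log2 (points, with SE from the fit to the varying genes) of the varying members of 6 lists. Filled points passed over all 19505 genes and open points did not; all members shown lie above 0, from 0.056 (H2-K1) to 1.13 (C4b).

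Of the 16 fixed genes, most of them hypothalamic peptides, 14 were measured and 8 varied; 2 passed over all genes (C4b and Gfap), and 4 when adjusted over the list alone. Avp, which encodes vasopressin, had 9.06 ± 0.19 in Young and 9.68 ± 0.23 log2 in Old (SD, n = 5), higher by 0.62 (SE 0.13) with no overlap between the groups; its adjusted p was 0.182 over all genes and 0.00353 in the varying genes alone. Sst, which encodes somatostatin, was lower, at -0.16 (SE 0.045; adjusted p = 0.465 over all genes and 0.0272 in the varying genes alone). Npy was higher by 0.20 (SE 0.078), Pmch by 0.07 (SE 0.051), and Hcrt and Trh were at -0.09 (SE 0.051) and -0.04 (SE 0.064); none of these 4 passed in either fit. Pomc (6.32 log2), Cartpt (8.70), Gnrh1 (6.23), Crh (6.94) and Ghrh (6.98) were collapsed and Oxt (9.49) nearly so, and the values cannot show whether age changed them.

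**Figure D4:**
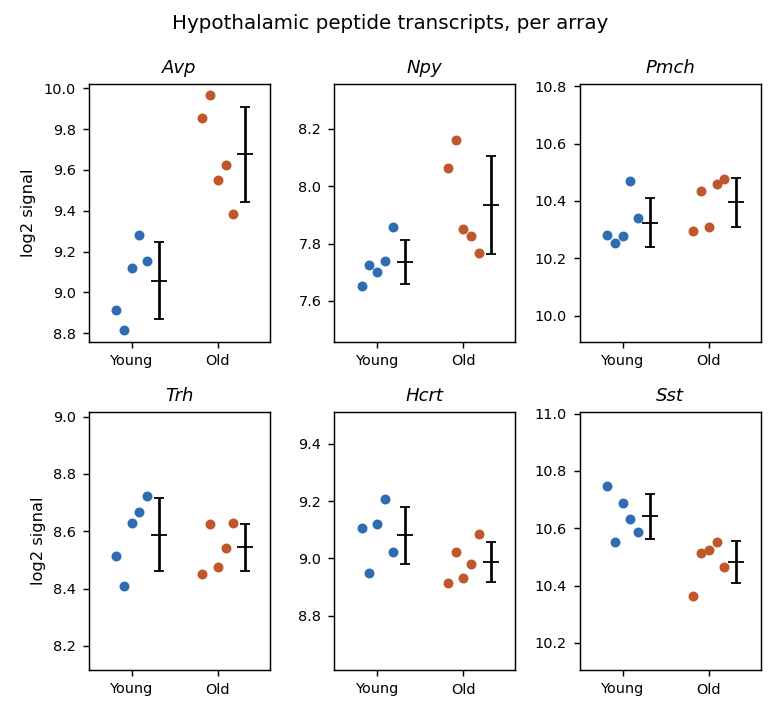
Log2 signal of each array (points) for 6 hypothalamic peptide genes, with the group mean and SD (bars, n = 5). The Old values of Avp lie above all Young values, a difference of 0.62 log2; the groups overlap in the other 5 panels.

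The feeding list (adjusted p = 0.437) and the neuroendocrine list (adjusted p = 0.854) did not pass. Lists of myelinating oligodendrocytes (8 varying members, 4 higher and 4 lower; adjusted p = 0.893), endothelium (0.937), synaptic vesicle genes (0.106), immediate early genes (5 varying members, all higher; 0.104) and heat shock genes (4 varying members, all lower; 0.327) did not pass over all genes either. For 10 of the 41 lists tested, among them those for lymphocytes, the circadian clock, tanycytes, ependyma, NF-kB signalling, cholesterol synthesis and the proteasome, 0 members varied.

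Single arrays stood apart for transcripts known from other tissues. Young 5 had Ttr, the transthyretin of choroid plexus, at 12.44 log2 against a mean of 7.34 ± 0.33 (SD, n = 9) in the others, and Kl at 8.50 against 6.56. Young 3 had the liver transcripts Mup2 at 7.35 and Alb at 6.87 log2, where the other 9 arrays had at most 6.40 and 6.34; Mup genes are similar in sequence, so that signal may come from other members of the family. The dopamine transporter gene Slc6a3 ran from 6.91 to 8.51 in Young and from 6.65 to 8.90 in Old. These genes, and the striatum comparison that follows, were chosen after their values were seen. Over the 4 varying members of the fixed striatum list, Young 1, Young 2 and Old 3 had a mean of 8.19 to 8.29 log2. The other arrays had 7.76 to 8.02, and the cause of this difference was not tested. Without Young 3 and Young 5, 22 genes rose and 2 fell over all genes, and 57 and 17 in the varying genes alone.

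**Figure D5:**
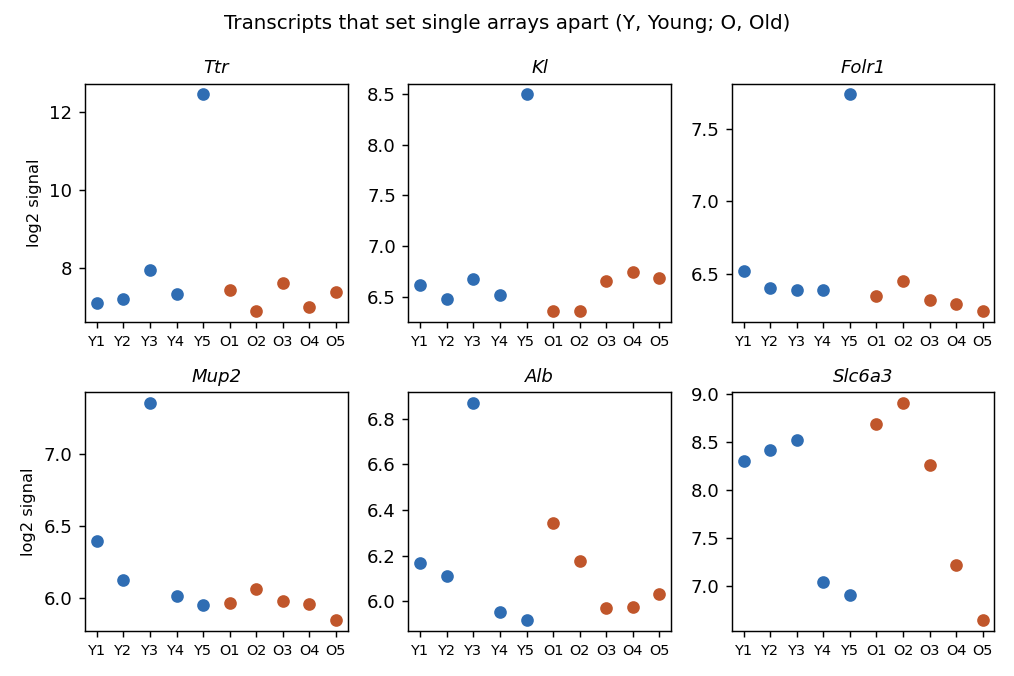
Log2 signal on each of the 10 arrays for choroid plexus (Ttr, Kl, Folr1), liver (Mup2, Alb) and dopaminergic (Slc6a3) transcripts. Young 5 stands apart for the choroid plexus genes, with Ttr at 12.44, and Young 3 for the liver genes, with Mup2 at 7.35.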

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

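The tests of the choroid plexus markers and of the label of Young 5, and the fit without Young 3 and Young 5 together, were chosen after the values they use had been seen. For each of 31 named varying genes and 16 list means, the lowest or highest array of a group was compared with its nearest neighbour. Of the 94 groups 5 had an array far from the rest (a gap above 0.71 of the range), and chance gives about 1 in 20 groups. Ifit3b was lowest in Young 3, at 7.01 against a nearest value of 7.17 log2. Young 5 was highest for Gfap (9.13 against 8.90) and for Ccnd2 (6.75 against 6.67). Kcnj10 was lowest in Old 1 (9.19 against 9.45), and without that array its difference was -0.42 and still passed; without Young 3 and Young 5 it was -0.48 and did not.

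The mean of the varying choroid plexus markers was 8.50 log2 in Young 5, where the next Young array had 6.83. All 6 varying markers of that list, fixed before the data were examined, were highest in Young 5: Ttr was 34.4-fold above the mean of the other 9 arrays, Kl 3.82-fold, Folr1 2.58-fold, Kcne2 2.27-fold, Otx2 1.54-fold and Clic6 1.52-fold. The other 4 of the 10 measured markers did not vary, so their values cannot bear on it. Choroid plexus lines the roof of the third ventricle, whose lower walls the hypothalamus forms, and a piece of choroid plexus in that sample is a candidate source. A wrong age label is argued against: over the 30 varying genes called in a fit without Young 5, that array lay at 0.030 (SD 0.29) on a scale from 0 (the other Young arrays) to 1 (Old). No biological explanation was tested, since the labels set Young 5 apart in nothing.

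Of the fits that compared the ages, unnamed probe sets entered only the alternative fit to all probe sets, and 65 of them varied. Of these, 11 rose and 0 fell in that fit, the largest by 1.01 log2 (adjusted p = 0.0148).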

How the results depend on the processing

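The alternatives that used the varying genes, an SD of at least 0.05, Young 3 and Young 5 left out, or Slc6a3 as a covariate were added after seeing the data. The fit to all genes gave 37 genes higher and 6 lower. It gave 154 and 6464 with quantile normalization, which raised the median SD of collapsed genes from 1e-05 to 0.00074 log2; 6472 of those calls were collapsed genes. An unmoderated test gave 18 and 2, an adjusted p under 0.01 gave 21 and 2, and a fold of at least 1.5 gave 10 and 0, where the last 2 are stricter by construction. A trended robust prior gave 10 lower. The varying genes alone gave 68 and 31, those with an SD of at least 0.05 gave 65 and 28, and leaving out Young 3 and Young 5 gave 22 and 2. Leaving out single arrays gave 25 to 37 higher and 4 to 9 lower. The other alternatives, apart from the replicate block below, stayed within 1.5 times. Quantile normalization thus added mostly collapsed genes, and in the varying genes alone it gave 66 higher and 36 lower. Apart from this and the stricter thresholds, the cause of the changed counts was not tested.

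With the replicate number as a block, 10 genes rose and 1 fell, 10 of them among the 43. Same-numbered samples deviated from their group means with correlations of 0.0037, -0.083, -0.22, 0.11 and 0.28, and 1 number of 5 was the best partner of its own. These values give no sign that the numbers pair the samples, but 5 correlations are too few to exclude it. In the varying genes alone, the counts of 68 and 31 stayed within 1.5 times except that leaving out Young 3 and Young 5 gave 17 lower and leaving out Young 1 gave 20; single arrays left out gave 57 to 64 higher and 20 to 37 lower.

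Of the 41 lists 5 passed. Median centring gave 17, all ranked higher in Old, and raised the median SD of collapsed genes to 0.0011. The 17 include striatum, whose 4 varying members were all lower, and choroid plexus, with 5 of 6 lower. A pass under centring is therefore not evidence that the members of a list rose. The block gave 3, an estimated correlation 2, and Young 3 and Young 5 left out 2. With fry 8 passed: the same 5, astrocytes (lower in Old), interferon-stimulated genes and MHC class II. Of the 4 varying members of the astrocyte list 2 were higher and 2 lower, and Ctss was the only varying MHC class II member. Leaving out single arrays gave 2 to 6, with 2 without Old 3 and 3 without Young 3. The beta protocadherins and reactive astrocytes passed under each of these alternatives; with an estimated correlation in the varying genes alone, reactive astrocytes did not (adjusted p = 0.219). Of 558 values of the 31 named varying genes, 495 kept direction and side of the threshold, 1 lost its difference (Fth1 with quantile normalization), 45 no longer passed, 16 newly passed and 1 turned: Trh was at 0.016 without Young 3 and Young 5. No detection call was used, so what dim signal limits was not tested.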

Other observations

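The genes in the first 2 paragraphs were chosen after their values were seen, and so were the fit to the varying genes and the tests of the 2 patterns below, apart from the camera tests over all genes; the counts of splits were planned. In the fit to the varying genes, Fcgr3 rose by 0.50 (SE 0.074) and Fcgr2b by 0.38 (SE 0.037), which encode Fc receptors, Ly86 by 0.33 (SE 0.037) and Spi1, the myeloid transcription factor PU.1, by 0.18 (SE 0.06). These 4 genes were in none of the fixed lists, and 0 of the 14 homeostatic microglia genes varied. Fbln5, Ccn1 and Efemp1, which encode matrix-associated proteins, rose by 0.76 (SE 0.16), 0.56 (SE 0.11) and 0.51 (SE 0.099), while the fixed list of collagens and extracellular matrix did not pass over all genes (adjusted p = 0.963), with 1 varying member higher and 1 lower. The lipocalin gene Apod rose by 0.58 (SE 0.071). Bcas1 rose by 0.47 (SE 0.051) and Gatm by 0.41 (SE 0.043), while Cldn11 differed by -0.24 (SE 0.057), Fa2h by -0.21 (SE 0.064) and Gpr17, a marker of newly forming oligodendrocytes, by -0.20 (SE 0.041). Cldn11 and Fa2h are in the myelinating oligodendrocyte list, of whose 8 varying members 4 were higher and 4 lower. In this fit 1 member of that list rose and 2 fell.

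Falls in the same fit included Fabp7 at -0.41 (SE 0.11), Ncan at -0.38 (SE 0.067) and Gja1 at -0.14 (SE 0.045). The fatty acid desaturase genes Fads1 and Fads2 were at -0.22 (SE 0.041) and -0.11 (SE 0.032). The presynaptic genes Syn1 and Syngr3 were at -0.15 (SE 0.03) and -0.13 (SE 0.033), and Cnih2, an auxiliary subunit of AMPA receptors, was at -0.14 (SE 0.032). Lcn2 was high on 2 arrays, 7.34 in Young 3 and 7.95 in Old 2, and did not pass.

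Over 100 splits of the 10 arrays into 5 and 5, drawn from all such splits with the real one included, only 1 split, Old against Young itself, gave as many results. The real split gave 43 genes over all genes tested and the highest other 0; in the varying genes alone these were 99 and 2, and for lists past the threshold 5 and 2. A chance division of the arrays is thereby made less likely as the source of these counts, but not excluded. With 100 splits the share cannot fall below 1 in 100, and each other split mixes Old with Young arrays, which widens the spread within its groups. The splits also cannot tell age from anything else that differed between the groups.

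The shared spread of 1e-05 is the first pattern. Rounding is argued against, since 99.8% of collapsed probe sets had 10 distinct values. Dim signal as the only cause is argued against too, since 89.8% of the brightest 10% of probe sets were collapsed. Over all probe sets that share was 97.9%, so bright ones escaped more often, and a part played by brightness is not excluded. Over 53 pairs of collapsed probe sets of the same gene the median correlation was 0.30, against -0.23 to 0.26 for random pairs (permutation p = 0.0001, the smallest that 10000 resamples can give), although 5 pairs lay above 0.9, where shared probes may be the reason, and the rest had a median of 0.20. Among genes that did not vary, 3 of 39 lists passed, all higher in Old: complement (camera adjusted p = 0.0264), disease-associated microglia (0.0264) and myelinating oligodendrocytes (0.0142). Thus 2 of the 5 lists past the threshold over all genes also passed there, while reactive astrocytes (0.953), MHC class I (0.836) and beta protocadherins (0.266) did not. The genes tested there include the 111 between collapsed and varying. Among them are C1qc of complement and Trem2 of disease-associated microglia, which passed singly over all genes. These list results thus cannot show whether collapsed probe sets kept an age pattern, and how much pattern was kept stays open. A candidate explanation is a summarisation that shrank probe sets without a common signal to a fixed small spread, as factor-analysis methods may do; the method is not given in the sources used here, so this stays a hypothesis.

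The second pattern concerns 4 genes chosen after their values were seen, for which no list of cold-induced genes was tested. Rbm3 and Cirbp, RNA-binding proteins induced by cold, rose by 0.78 (SE 0.13) and 0.22 (SE 0.06) in the varying genes, and Hsph1 and Chordc1, which heat induces, were at -0.22 (SE 0.053) and -0.19 (SE 0.048). No single array carried these differences, since at least 84.8% of each was left without any 1 array. Young 3 and Young 5, with their liver and choroid plexus transcripts, did not carry them either, since at least 76.7% was left without both. Genes chosen with their differences in view are likely to keep them, so these shares lend the pattern no further weight. Lower heat-shock expression with age stays open: the heat shock list, which holds Hsph1, did not pass, with a camera adjusted p of 0.327 over all genes and 0.168 in the varying genes. A lower temperature of the aged animals or a difference in handling may also play a part, and neither was tested.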
